A study of Arabidopsis thaliana with 9 samples.

How the data were processed

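H3K4me3, the trimethylation of lysine 4 of histone H3 that marks the 5′ part of transcribed genes, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in 12-day-old Arabidopsis thaliana seedlings of 3 genotypes. These were the wild-type accession Col-0, the mutant jmj28-2 and the mutant atx1/2, each with 2 H3K4me3 libraries. Seedlings were grown in long days on sucrose-containing medium, per the labels' protocols. The series also has 3 H3 samples, 1 per genotype, whose data were not analysed here. The labels do not say that the 2 libraries of a genotype came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

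The authors deposited 1 peak list per H3K4me3 library, with the position of each peak and a peak score. Bowtie2 2.2.8, MACS 1.4, ChIPseeker, deepTools 2.4.1 and the genome build TAIR10 are named in the submitters' processing notes, without their roles. The score column was the authors' value for each peak; MACS 1.4 writes a transformed p-value there, relative to a control library that no label names. The lowest score in a list lay between 20.01 and 20.08. Scores were used to rank peaks within a list, or to filter every list at the same minimum of 100. No region was tested for a change in score. Median scores of whole lists are set side by side only in the part on flagged results. The lists give no read counts, so the sequencing depth of each library is unknown and no counting interval is given. Peaks had been called in each library by itself, so replicate lists could be compared.

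Peak starts were converted to positions counted from 1, and peaks on chromosomes 1 to 5 were kept. Peaks of the 6 lists that shared at least 1 bp were merged into 14670 regions. The bp of peak in each region were summed per library. A region lost in a mutant had a peak in both Col-0 libraries and in neither mutant library, and a gained region had the reverse. Both counts were set beside those from the other splits of the same 4 libraries into 2 against 2. Changes in length were tested with limma 3.58.1 in R 4.3.3 on log2(bp of peak in the region + 200), with all 6 libraries in 1 fit (3 residual degrees of freedom). The 14394 regions with a peak in at least 2 libraries were tested, with a Benjamini-Hochberg adjusted p threshold of 0.05. A log2 change understates the change of short regions because of the pseudocount, and none is given against a genotype with no peak. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

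The procedure was tested on simulated data for jmj28-2 against Col-0, in which 100 of 14394 regions had their peak removed and 100 more were shortened or lengthened. All 100 removed peaks were called, as were 42 of 50 regions multiplied by 0.7 and 33 of 50 multiplied by 1.3. Of 13283 unchanged regions with a peak in every library, 9 were called. The noise of these regions was drawn from a normal distribution, with the largest spreads capped. Jumps in length, as where neighbouring peaks split or merge, were not simulated, so the error in real regions may be higher. Of 911 unchanged regions with a peak in some libraries only, 72 were called, so the adjusted p of a region without a peak in some libraries is too small. For lost and gained regions the counts from other splits are therefore the measure of error between replicate libraries. Each side of such a split has 1 library of each genotype, so a fault common to both libraries of a genotype is not measured.

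Genes were assigned from a RefSeq gene table of the assembly TAIR10.1, which gives no strand. The names of the builds differ, so every printed coordinate is that of a peak or region (TAIR10). The table was used after a check in 116 windows of 1000 kb, of which 115 fitted the peaks best with a shift under 400 bp. A region took the name of the protein-coding gene with the largest overlap, of at least 200 bp, and 14382 regions had such a gene. Transcription start sites could not be placed without strand, so the planned measures around them were replaced by overlap with gene bodies, and exon, intron and UTR annotation was not used. Peaks on the chloroplast genome were left out of all regions.

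The genes named in the text follow a rule written before the data were examined, with 1 change. In the rule, and in the plan for the gene lists, a gene was placed in a region by its transcription start site. Overlap with the gene body was used instead. JMJ28, ATX1, ATX2, CO, FT and FLC are given in every case. For each mutant the 10 shortened and the 10 lengthened regions with the largest change, past the threshold, with the same sign in all 4 pairs of libraries and with a gene symbol, are named. Up to 4 members with the largest change are taken per gene list. Genes named outside this rule were chosen after their values were seen, as stated beside them. The 12 gene lists, with 242 genes, were also fixed before the data were examined, and all 242 matched the table. They were tested with limma's camera (preset correlation 0.01, and an estimated correlation) and fry over lists with at least 3 regions. The alternatives covered the score minimum, the number of peaks per list, merging within 300 bp, the pseudocount, the filter, centring, the variance model, the replicate number, the omission of each library and the assignment of 1 Col-0 library to each mutant. Where an alternative left peaks out, a named region kept its bounds from the full lists, and where peaks were merged it was followed to the region with the largest overlap.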

Results

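H3K4me3 peak lists were compared between wild-type seedlings, jmj28-2 and atx1/2. JMJ28 encodes a JmjC-domain protein of the histone demethylase family, and ATX1 and ATX2 encode Trithorax-type H3K4 methyltransferases. The comparison asked where H3K4me3 depended on JMJ28 or on ATX1 and ATX2, and whether the same places depended on both. Each genotype had 2 libraries.

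H3K4me3 covered a similar set of genes in the 3 genotypes. The Col-0 libraries had peaks on 17031 and 17045 of 27432 protein-coding genes, the jmj28-2 libraries on 16838 and 16876, and the atx1/2 libraries on 17082 and 17069. Between 98.0% and 98.2% of the peaks of each library lay on a protein-coding gene. Col-0 had 14343 and 14291 peaks, jmj28-2 had 14338 and 14306, and atx1/2 had 14492 and 14493. Peaks were slightly narrower in the mutants, with median widths of 1839 and 1858 bp in Col-0, 1801 and 1820 bp in jmj28-2 and 1818 and 1812 bp in atx1/2. Peaks covered 29.4 ± 0.128 Mb (SD, n = 2) in Col-0, 28.7 ± 0.222 Mb in jmj28-2 and 29.0 ± 0.0896 Mb in atx1/2. The libraries of either mutant did not overlap those of Col-0 in width or covered length. The exact permutation test with 2 libraries against 2 cannot go below p = 0.333, the value reached for both measures in both mutants.

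Of the 14670 regions, 13483 (91.9%) held a peak in all 6 libraries and 276 in a single library. Covered bases of the libraries of 1 genotype had a Jaccard index of 92.2% ± 0.458 (SD over 3 pairs), against 90.9% ± 0.284 over the 12 pairs of different genotypes. Of the 15 ways to pair the 6 libraries, the real pairing had the highest mean index, 92.2% against 91.5% for the next (exact p = 0.0667, the smallest the design allows).

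The mutated genes JMJ28, ATX1 and ATX2, and the flowering genes CO and FLC, lay in regions with a peak in every library. JMJ28 had a peak (chromosome 4, 11410712 to 11412788, TAIR10) of 1957 ± 7.07 bp (SD, n = 2) in Col-0, 2038 ± 36.1 bp in jmj28-2 and 1950 ± 24.8 bp in atx1/2. The peak of ATX1 (chromosome 2, 13460841 to 13462842) measured 1954 ± 68.6 bp, 1850 ± 58.7 bp and 1852 ± 19.8 bp in the same order. The ATX2 region (chromosome 1, 1753659 to 1755793), which also held SPPL5, measured 2103 ± 28.3 bp, 1990 ± 31.8 bp and 2046 ± 3.54 bp. CO, the photoperiod-dependent activator of flowering, lay in a region (chromosome 5, 5168318 to 5171016) whose gene of largest overlap was bZIP3 and which also held AT5G15843, so its peak is not that of CO alone. It had 2585 ± 11.3 bp of peak in Col-0, 2577 ± 49.5 bp in jmj28-2 and 2510 ± 74.2 bp in atx1/2. FLC, the floral repressor (chromosome 5, 3178485 to 3179829), had 1334 ± 12.0 bp, 1316 ± 6.36 bp and 1266 ± 46.0 bp. No library had a peak on FT, the florigen gene. For these 5 genes with a peak the limma adjusted p lay between 0.631 and 0.998 in both mutants. The test was of peak length, and the lists give no read counts. An unchanged length therefore does not show an unchanged H3K4me3 level, here or in the gene lists below. A peak list does not show whether an allele is mutated, so JMJ28, ATX1 and ATX2 do not check the genotype labels here.

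In jmj28-2, 141 regions lost their peak and 74 regions gained one. The lost regions named by the rule included those of CRK29, CRK21 and B120, which encode receptor-like kinases, and of RLP23 and RLP38, which encode receptor-like proteins. The CRK29 region (chromosome 4, 11403176 to 11406566) had 3349 ± 8.48 bp of peak in Col-0 and 3208 ± 162 bp in atx1/2 but none in jmj28-2. RLP23 (chromosome 2, 13859523 to 13862901), the receptor for a fragment of microbial necrosis-inducing proteins, had 3307 ± 39.6 bp in Col-0 and no peak in either mutant. ABCG14, a cytokinin transporter gene, had 2958 ± 50.2 bp in Col-0, but 1 of its Col-0 peaks was absent with equal numbers of peaks per list. The chr31 region, over the gene of a chromatin remodelling factor of the CLASSY family, had 2780 ± 124 bp. The other lost regions named by the rule were those of DAG2, a Dof transcription factor (2161 ± 91.9 bp), RPA70B, a replication protein A subunit (2146 ± 71.4 bp), and ZF14 (1952 ± 110 bp).

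Among gained regions in jmj28-2, the pectin methylesterase gene ATPMEPCRC (chromosome 3, 4766698 to 4769695) had 2840 ± 87.0 bp of peak, against none in Col-0. Fatty acid elongase gene KCS5 (chromosome 1, 8938510 to 8940680) had 2065 and 2171 bp and the D-type cyclin CYCD4;2 had 1404 ± 31.8 bp, and neither had a peak in Col-0 or atx1/2. FTSH6, a chloroplast protease gene, IQD6, ABCG6, BBX27, GIS, SGR9 and GDU1 were the others named by the rule, with 1940 ± 315, 1654 ± 212, 1630 ± 159, 1616 ± 135, 1560 ± 37.5, 1411 ± 69.3 and 1408 ± 33.2 bp of peak in jmj28-2. The limma adjusted p of the 20 named regions ranged from 3.98e-06 to 0.000359. The other splits of the 4 libraries gave 18 to 27 such regions each. Permuting the labels of all 6 libraries within regions gave at most 74 lost and 72 gained, so the 74 gained regions barely passed this measure.

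Of the lost regions, 3 lay side by side next to JMJ28, a run noticed after the values were seen. They were those of RK3 (chromosome 4, 11391522 to 11393462), B120 (11395895 to 11398031) and CRK29, all receptor-like kinase genes, and spanned 15045 bp. RK3 had 1753 ± 7.07 bp of peak in Col-0, none in jmj28-2 and 1860 ± 58.7 bp in atx1/2. The JMJ28 peak, 4.146 kb away, and the PUB8 peak on the other side (2110 ± 11.3 bp in Col-0 and 2137 ± 35.4 bp in jmj28-2) were kept. No jmj28-2 library had a peak between them. Without these 3 regions 138 were lost in jmj28-2.

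**Figure D1:**
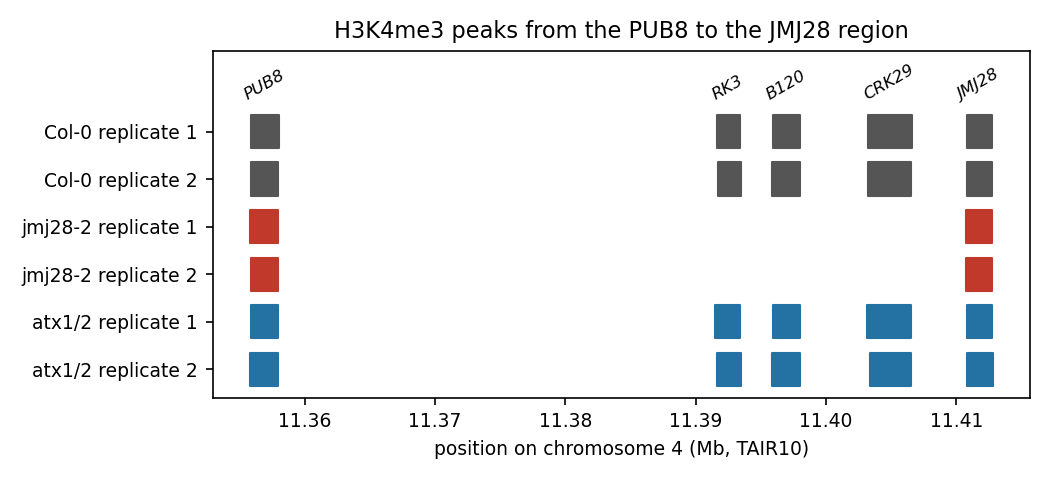
Bars show the peaks of each library (rows) along chromosome 4 around JMJ28 (x axis, position). The peaks over RK3, B120 and CRK29 stand in the Col-0 and atx1/2 libraries and in neither jmj28-2 library.

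**Figure D2:**
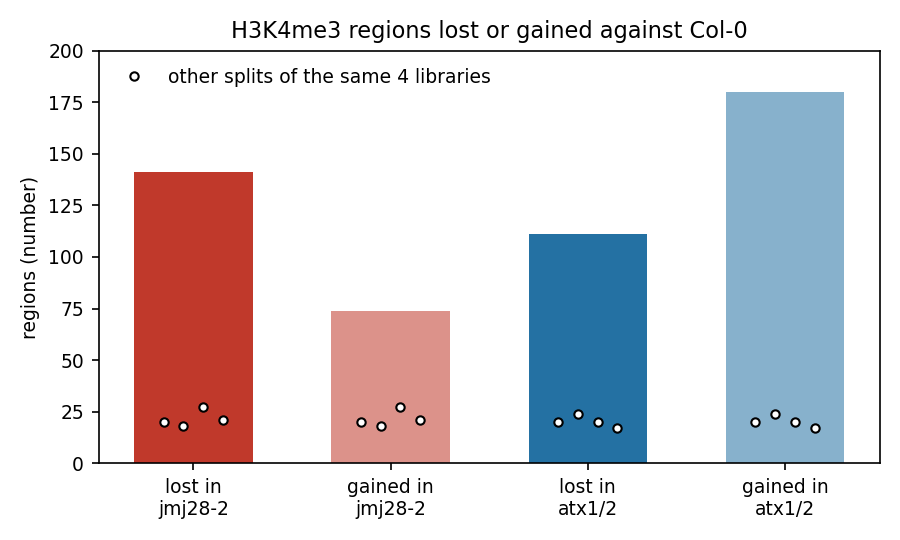
Bars give the number of H3K4me3 regions lost or gained in each mutant against Col-0 (y axis, regions), and open circles give the counts for the other splits of the same 4 libraries. The bars stand at 141 and 74 for jmj28-2 and at 111 and 180 for atx1/2, and the circles between 17 and 27.

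In atx1/2, 111 regions lost their peak and 180 gained one. The longest lost peak with a gene symbol was that of CSLD5, a cellulose synthase-like gene (chromosome 1, 594595 to 598922), with 4269 ± 32.5 bp (SD, n = 2) in Col-0, 4221 ± 151 bp in jmj28-2 and none in atx1/2. PLE, which encodes a microtubule-associated protein of the cytokinetic phragmoplast, had 1933 and 3880 bp in the Col-0 libraries and no peak in atx1/2. The fatty acid elongase gene KCS3 (2016 ± 65.0 bp in Col-0), the AT-hook gene AHL22 (1923 ± 59.4 bp) and the subtilase gene SBTI1.1 (2260 ± 436 bp) also had a peak in Col-0 and jmj28-2 but none in atx1/2. RLP23, ABCG14, RLP38 (2589 ± 184 bp in Col-0) and AAE18 (1934 ± 220 bp) had no peak in either mutant. ICME-LIKE2 had 1889 ± 67.9 bp in Col-0 and none in atx1/2.

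Gained regions in atx1/2 included those of the methionine gamma-lyase gene MGL (1786 ± 146 bp) and the endoglucanase gene CEL2 (1768 ± 92.6 bp), with no peak in Col-0 or jmj28-2. ATPMEPCRC (2960 ± 24.8 bp) and GIS (1728 ± 37.5 bp) were gained in both mutants. These 4 regions stayed gained with the same number of peaks from every list, and the other 6 regions named by the rule did not. In that setting PYD4 (2357 ± 130 bp), FTSH6 (1956 ± 67.9 bp), CYP94B2 (1791 ± 32.5 bp) and PGL2 (1588 ± 102 bp) each lost the peak of 1 atx1/2 library. MEE20 (1606 ± 68.6 bp) and the pectin methylesterase gene PME2 lost both. PME2 (chromosome 1, 20098332 to 20100888) had 2496 ± 17.7 bp in atx1/2 and 1329 ± 15.6 bp in jmj28-2 in the full lists, but a peak in jmj28-2 alone in that setting. Of all 180 gained regions 103 stayed gained there, and 103 of the 111 lost regions stayed lost. The limma adjusted p of the 20 regions named for atx1/2 ranged from 2.16e-06 to 0.00997. Other splits of the 4 libraries gave 17 to 24 regions each, and permuted labels of all 6 libraries at most 73 lost and 69 gained. With the same number of peaks taken from every list, 14291, the balance turned to 151 lost and 112 gained in atx1/2, while jmj28-2 had 137 and 73. At a score of 100 or more it was 78 lost and 193 gained in atx1/2, and 118 and 101 in jmj28-2. Most of these were not regions lost or gained in the full lists, because a peak kept in the full lists can fall under that score.

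Most lost and gained regions held weak peaks. Their median score percentile within the lists that held them was 3.50 and 2.87 for regions lost and gained in jmj28-2, and 3.45 and 2.85 for those lost and gained in atx1/2. A score of 100 or more in both libraries that held the peak was reached by 6 of 141, 0 of 74, 4 of 111 and 4 of 180 of these regions. RK3, B120 and CRK29, the run beside JMJ28, were among the 6 lost in jmj28-2. In the order of those 4 groups, 8, 7, 7 and 21 regions held no protein-coding gene.

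Length also differed in regions that held a peak in all 6 libraries, and the regions named for this were chosen after their values were seen. The region of CYCD1;1, a D-type cyclin gene (chromosome 1, 26439423 to 26442281), was longer in both mutants, with 1386 ± 7.78 bp (SD, n = 2) in Col-0, 2811 ± 7.07 bp in jmj28-2 and 2730 ± 79.2 bp in atx1/2. The log2 change was 0.93 ± 0.028 (SE) in jmj28-2 and 0.89 ± 0.028 in atx1/2 (limma adjusted p = 0.000199 and 0.000187). PAL1, which encodes a phenylalanine ammonia-lyase (chromosome 2, 15557455 to 15560818), was shorter in jmj28-2, with 2186 ± 19.1 bp against 3230 ± 4.95 bp in Col-0 and 3292 ± 8.48 bp in atx1/2. Its log2 change in jmj28-2 was -0.52 ± 0.022 (limma adjusted p = 0.000719), and the mutants differed by 0.55 (adjusted p = 0.000515). The MET1 region, over the maintenance DNA methyltransferase gene, had 2019 ± 197 bp in Col-0 and 3372 ± 54.5 bp in jmj28-2 (limma adjusted p = 0.0219), but neither jmj28-2 peak reached a score of 100. RLP2 and 2 neighbouring genes shared a region that was shorter in atx1/2, with 2034 ± 91.2 bp against 4164 ± 102 bp in Col-0 and 4100 ± 26.2 bp in jmj28-2 (log2 change -0.97 ± 0.039, limma adjusted p = 0.000486).

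Several of the shortened regions spanned neighbouring genes, and the length was lost beside the gene with the largest overlap. The region over WRKY18, a defence transcription factor gene, and AT4G31805 (chromosome 4, 15382785 to 15386931) had 3989 ± 223 bp in Col-0, 2054 ± 6.36 bp in jmj28-2 and 2134 ± 70.0 bp in atx1/2. Its log2 change was -0.89 ± 0.047 and -0.84 ± 0.047 (SE; limma adjusted p = 0.00194 and 0.00192), while over the WRKY18 gene body alone the change was -0.13 and -0.08 and did not pass the test. SUVH1, a methylation-binding SET-domain gene, shared its region with NAS1, and this region fell from 3274 ± 9.19 bp in Col-0 to 1704 ± 75.7 bp in atx1/2, but with a change of -0.05 over the SUVH1 body and of -0.06 at a score of 100 or more. SNX1, a sorting nexin gene, shared with CYC1BAT a region of 2582 ± 32.5 bp in Col-0, 1612 ± 26.2 bp in jmj28-2 and 1664 ± 20.5 bp in atx1/2, and over SNX1 alone neither mutant passed the test. The region of VPS54 was also shorter, with 3473 ± 252 bp in Col-0, 2152 ± 30.4 bp in jmj28-2 and 2114 ± 36.8 bp in atx1/2, and no value over its gene body is given here. A region over ORC2, an origin recognition complex gene, and AGD7 had 2284 ± 40.3 bp in Col-0, 4231 ± 399 bp in jmj28-2 and 4204 ± 27.6 bp in atx1/2 (limma adjusted p = 0.0109 and 0.00853). Neither call held at a score of 100 or more, with changes of -0.08 and -0.07, and that in atx1/2 was also lost with equal numbers of peaks. CSD2, a chloroplast superoxide dismutase gene, shared with ATCHX8 a region that had 3558 ± 292 bp in Col-0 and 1974 ± 36.1 bp in jmj28-2 (limma adjusted p = 0.029), a call that was lost without any 1 of the 6 libraries.

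**Figure D3:**
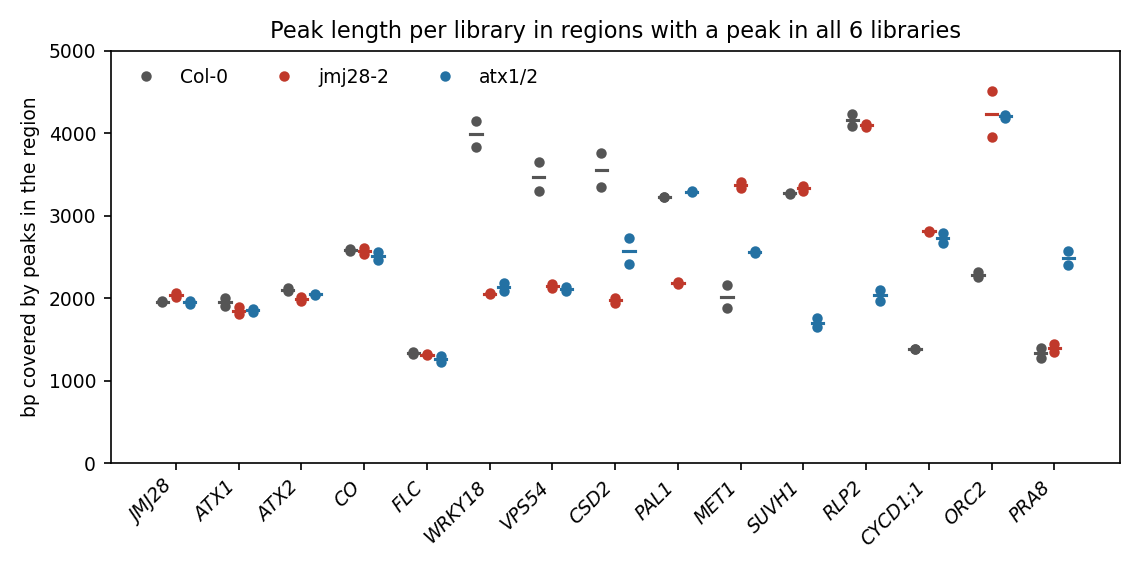
Points give the bp covered by peaks in each library (y axis, bp) and short lines the mean of the 2 libraries, for the regions that hold the genes named. The points of JMJ28, ATX1, ATX2, CO and FLC lie close together, while CYCD1;1 stands at 1380 and 1391 bp in Col-0 and at 2674 bp or more in the mutants.

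Across all tested regions limma called 207 in jmj28-2, 141 shortened and 66 lengthened, and 267 in atx1/2, 126 shortened and 141 lengthened. With equal numbers of peaks per list the atx1/2 calls divided into 156 shortened and 96 lengthened. Most calls were regions without a peak in some library. Among the 13483 regions with a peak in all 6 libraries, 36 were called in jmj28-2 (30 shortened, 6 lengthened) and 49 in atx1/2 (37 shortened, 12 lengthened). In these regions the median log2 change was -0.02 in jmj28-2 and -0.01 in atx1/2, and 64.2% and 59.0% of regions were shorter. Once each library was centred on its median the median over all tested regions was 0.01 in both mutants. Centring removes such a shift by construction, so this value does not test it. When only the 4 libraries of a comparison were fitted, 239 and 351 regions were called in limma, against 42 to 51 and 36 to 45 for the other splits. A fit with a mean-variance trend and robust variances called 129 (84 shortened, 45 lengthened) and 119, where the balance in atx1/2 turned to 69 shortened and 50 lengthened. Without 1 or the other Col-0 library the lengthened regions numbered 138 and 118 in jmj28-2 and 225 and 207 in atx1/2.

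The mutants differed from each other directly in 228 regions, 68 shorter and 160 longer in atx1/2 than in jmj28-2 (limma, adjusted p threshold 0.05). With equal numbers of peaks per list this was nearly even, 99 shorter and 112 longer, and with trend and robust variances it was 52 and 68. CSLD5, KCS3 and AHL22 were among those shorter in atx1/2, with limma adjusted p of 2.57e-06, 2.70e-06 and 1.58e-05. With equal numbers of peaks AHL22 had 1963 and 0 bp in the jmj28-2 libraries, while CSLD5 and KCS3 kept both jmj28-2 peaks. CRK29, CRK21 and DAG2 were among those longer in atx1/2, with 3.23e-06, 3.43e-06 and 4.52e-06. In regions with a peak in all 6 libraries the calls were even, 16 shorter and 16 longer.

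The mutants also shared lost and gained regions. They had 50 lost and 46 gained regions in common, where independent lists would share 1.07 and 0.908. Permuting the library labels within regions gave 15.1 and 16.2 on average and at most 28 and 34. RLP23, ABCG14, RLP38 and AAE18 were among the regions lost in both, and ATPMEPCRC, FTSH6, IQD6, BBX27, GIS, GDU1 and PME2 among those gained in both. With equal numbers of peaks 44 of the 50 and 32 of the 46 were kept, without ABCG14, FTSH6, BBX27 and PME2. In the full lists a further 60 regions had no peak in jmj28-2 alone, 38 had none in atx1/2 alone, 14 had a peak in jmj28-2 alone and 83 in atx1/2 alone. In limma 72 regions were shortened in both mutants and 49 lengthened in both, with 1.23 and 0.647 for independent lists. Permuted labels gave 18.4 and 19.1, and at most 30 and 34. Without Col-0 replicate 1 or 2 the regions lengthened in both numbered 119 and 94. The log2 changes correlated across regions at Pearson's r = 0.52 and Spearman's rho = 0.49, and permuted labels gave a mean r of 0.50. Regions are not independent replicates. The covariance was 0.123 against 0.0748 for permuted labels. Both mutants were compared with the same 2 Col-0 libraries, which accounts for part of these values. With 1 Col-0 library for each mutant, a test chosen after seeing the data, r was 0.24 and 0.26 in the 2 assignments and rho 0.0777 and 0.0819. The mean r of 0.249 lay above permuted labels, which gave 0.00261 on average and at most 0.0798 in 100 draws. Regions called in opposite directions then numbered 28 and 25, against 64 and 63 shortened in both and 49 lengthened in both.

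**Figure D4:**
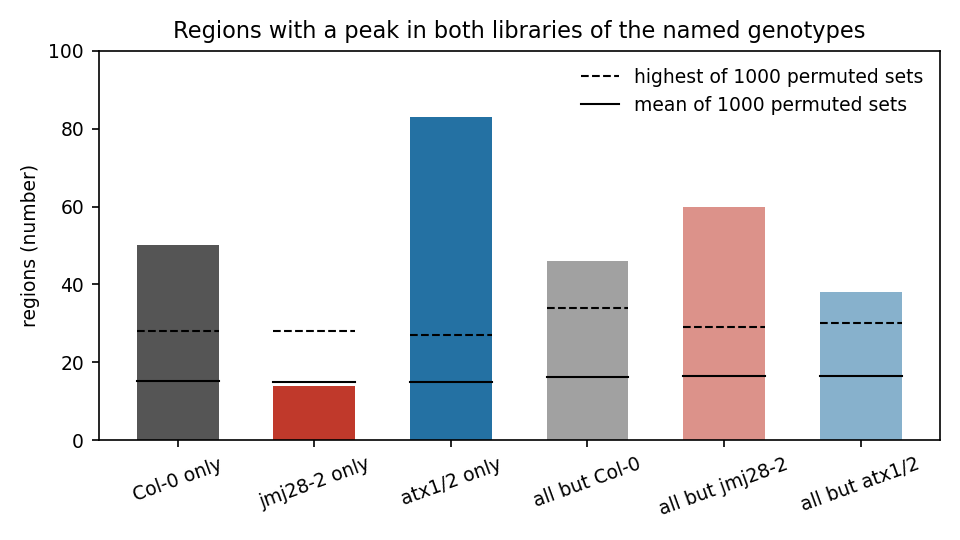
Bars give the number of regions (y axis) with a peak in both libraries of the genotypes named below and in no other library; solid and dashed lines give the mean and the highest of 1000 sets with permuted library labels. All classes except jmj28-2 only, at 14, lie above the highest permuted set.

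Most fixed gene lists kept their peaks, and few members passed the test. All 12 H3K4 methyltransferase and COMPASS genes and all 19 constitutive reference genes had a peak in all 6 libraries, and no member was called in either mutant. ATX5 had 2304 ± 105 bp in Col-0 and 2135 ± 55.2 bp in atx1/2 (log2 change -0.10), and UBQ10 had 3327 ± 173 bp and 3684 ± 264 bp (0.14). Of the 19 JmjC and LSD1-like demethylase genes 18 had a peak in all libraries and none was called. LDL2 and JMJ29 had log2 changes of -0.14 and -0.11 in atx1/2, and JMJ18 had -0.13 in jmj28-2. Among 44 flowering time genes, 33 had a tested region and none was called. Their largest changes were -0.13 for the photoreceptor gene CRY2 and 0.10 for SPA1 in jmj28-2, and -0.42 for the region LFY shares with a neighbour and 0.15 for SVP in atx1/2. Of the 18 circadian clock genes, all with a tested region, none was called. LNK2 lacked a peak in 1 jmj28-2 library, and CCA1 lacked one in 1 Col-0 and 1 jmj28-2 library.

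Of 30 abscisic acid and abiotic stress genes, 26 had a tested region and 1 was called, in jmj28-2. This was RD22, a dehydration-responsive gene with 1376 and 2431 bp in the Col-0 libraries, none in jmj28-2 and 2024 ± 168 bp in atx1/2 (limma adjusted p = 0.00899), and it did not pass when only 4 libraries were fitted. P5CS1, the proline synthesis gene, had 0 and 1195 bp in jmj28-2 against 1161 and 2904 bp in Col-0, and CBF2 and CBF3 lacked a peak in 1 atx1/2 library. Of 21 defence genes, 14 had a tested region, and the WRKY18 region described above was the 1 call in each mutant. Adjusted over the list alone, the region over MPK3 and NAXT1 was also called in both mutants, with log2 changes of 0.55 and 0.50 (2670 ± 130 bp in Col-0, 4004 ± 50.2 bp in jmj28-2 and 3872 ± 349 bp in atx1/2). This call was lost in both mutants without Col-0 replicate 1, and in jmj28-2 without jmj28-2 replicate 1. In fry, which asks whether a set moves at all, the defence list had a mixed adjusted p of 0.00118 in jmj28-2 and 0.00107 in atx1/2. The directional fry result of defence in jmj28-2 (adjusted p = 0.00399) was lost once each library was centred on its median (fry adjusted p = 0.920). It was also lost at a score of 100 or more (0.180) and with the replicate block (0.136). The mixed fry results of abscisic acid and abiotic stress in jmj28-2 (0.0175) and of photosynthesis in atx1/2 (0.0409) were lost with the replicate block. At a score of 100 or more the mixed result of abscisic acid and abiotic stress was lost too (0.159). Each of these results was also lost without some single libraries and kept without others. That of photosynthesis was lost only without a jmj28-2 library, which lies outside its comparison. Camera, which compares a list with other regions, gave 0.603 and 0.813 for defence. For the abscisic acid and abiotic stress list adjustment over the list alone gave the same call of RD22.

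The 25 photosynthesis genes with a tested region, of 28, had a median log2 change of 0.01 and a mean of 0.13 in jmj28-2, with no member called. Camera placed the list above other regions (adjusted p = 0.0095), but not with the correlation between genes estimated (adjusted p = 0.668 with an estimated correlation). The largest changes were those of LHCB1.3 (1.11), RBCS3B (1.08) and RBCS2B (0.73), with limma adjusted p of 0.76, 0.78 and 0.681, and both LHCB1.3 and RBCS3B lacked a peak in 1 Col-0 library. In atx1/2 camera gave an adjusted p of 0.813. No other list passed camera in either mutant.

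Most members of the Polycomb-silenced, pollen, seed storage and root lists had no peak in any library. No peak lay on 22 of 24 Polycomb-silenced developmental genes, on any of 5 pollen genes, on 11 of 14 seed storage genes or on 7 of 9 root genes. KNAT6 and CUC1 were the Polycomb-silenced genes with a peak, and the region CUC1 shares with AT3G15180 varied within Col-0 (1590 and 3402 bp). The seed storage genes with a peak, CRU2, OLEO4 and PER1, and the root genes with a peak, SCR and GL2, had one in every library, and none was called in limma over all regions. Adjusted over the list alone, the region PER1 shares with a neighbour was called in atx1/2, with 1627 ± 21.2 bp in Col-0 and 1492 ± 33.9 bp in atx1/2. The call was lost with centred libraries, with the replicate block and without any of 5 single libraries.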

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

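Data outside the comparisons raised 1 result, and all tests in this part were chosen after the result was seen. Peaks on the chloroplast genome, left out of every comparison, covered 31586 and 12440 bp in the jmj28-2 libraries, against 2027 and 4678 bp in Col-0 and 0 and 0 bp in atx1/2. In both jmj28-2 libraries this length was above that in the Col-0 libraries. What it reflects was not tested, and it is not read here as a change in H3K4me3.

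The loss of 3 neighbouring peaks beside JMJ28 in jmj28-2 was weighed first. Peaks near the calling limit did not account for it: the median Col-0 score percentile of the 3 regions was 28.9, while 95% of the other lost regions lay at 9.65 or below. In random draws of as many Col-0 regions, a share of 0.0023 had as many within 100 kb of JMJ28. The run included a strong peak, CRK29 at percentile 79.6, which is consistent with a deletion or another sequence difference linked to the jmj28-2 allele. The alternative that loss of JMJ28 protein removes the mark from its neighbours was not tested, and peak lists do not hold the reads that could separate these.

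The excess of gained over lost regions in atx1/2 was weighed next. Random presence at the calling limit did not account for the counts of 111 and 180, since the other splits of the libraries gave at most 24 regions. Whether the longer atx1/2 peak lists account for the direction stays open. Gained minus lost was -39 with the same number of peaks from every list. That setting leaves out the lowest-scoring peaks of the longer lists, and 103 of the 180 gained regions stayed gained there. It was 115 at a score of 100 or more. Median scores were 527 and 538 in atx1/2 against 469 and 460 in Col-0, and whether 1 minimum acts alike in these lists was not tested. Only 4 of the 180 gained and 4 of the 111 lost regions reached that score in both libraries that held the peak. Neither value therefore separates a biological gain from a difference in peak calling.

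The regions lost or gained in both mutants were weighed last. A peak in both Col-0 libraries alone was found in 50 regions, above the highest of the permuted sets, 28, so random presence in the Col-0 libraries did not account for them. A difference of the Col-0 plants, or of their single H3 sample, from both mutants remains possible, because regions with a peak in atx1/2 alone numbered 83 and a single genotype can thus stand apart by as much. A shared dependence on JMJ28 and ATX1 with ATX2 would give the same pattern, and no library here separates the explanations.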

How the results depend on the processing

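Each library was left out in turn, and a genotype left with 1 library was assumed to vary like the other groups. All values in this part rest on tests chosen in advance, except gene bodies, the 500 bp extension, merged peaks for the position of peaks, the omission of libraries outside the length tests and of the regions beside JMJ28, and 1 Col-0 library for each mutant, which were chosen after seeing the data. Windows around transcription start sites were planned and not run, because the gene table gives no strand. Among the comparisons, 339 alternative values stayed the same, 38 moved, 4 lost the call and 6 reversed. Staying the same did not require an equal value. The 339 include gene lists that did not pass camera, either with all libraries or without single ones. They therefore do not measure how many changes held. Of 91 called changes of named genes, 1451 of 1588 alternative values stayed the same, 132 lost the call and 5 reversed. A named region without any peak under an alternative has no value there, as for MEE20 with equal numbers of peaks. Depth is unknown, so its effect was not tested.

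The peak number, jmj28-2 minus Col-0, turned to -25 with peaks within 300 bp merged, and ranged from -21 to 31 without single libraries. The percent of peaks on a protein-coding gene, jmj28-2 minus Col-0, was 0.0486 at a score of 100 or more and -0.0425 to 0.0155 without single libraries. Peaks shared within minus between genotypes came to 0.881 with reciprocal overlap of 50%. Without single libraries, which relaxes the rule to 1 library, 207 to 231 regions were lost and 129 to 153 gained in jmj28-2, and 160 to 183 lost and 249 to 285 gained in atx1/2. With equal numbers of peaks 112 were gained in atx1/2. Length calls for jmj28-2, atx1/2 and the mutants against each other fell to 31, 44 and 26 with the test limited to regions with a peak in all libraries, and to 129, 119 and 120 with trend and robust variances. Without single libraries jmj28-2 had 239 to 312. Regions lengthened in both mutants numbered 53 to 119. The correlation of changes was 0.472 at a score of 100 or more and 0.466 to 0.616 without single libraries, and the covariance 0.136 and 0.123 to 0.179. With 1 Col-0 library for each mutant the correlation was 0.240 and 0.259 and the covariance 0.0691 and 0.0736, since the shared library no longer enters both changes. Photosynthesis in jmj28-2 had adjusted p = 0.668 with an estimated correlation, 0.0822 at a score of 100 or more and 0.00933 to 0.127 without single libraries. On the log2 scale, the ORC2 length change, jmj28-2 against Col-0, turned to -0.077 at a score of 100 or more, and the ORC2 length change, atx1/2 against Col-0, to -0.067 there and with equal numbers of peaks. The SNX1 length change, jmj28-2 against Col-0, turned to 0.011 over gene bodies. The MET1 length change, jmj28-2 against Col-0, came to -1.69 at a score of 100 or more; no jmj28-2 peak and 1 Col-0 peak were left there, so the pseudocount sets this value and it is no measured reversal. Except where fewer regions were tested or fewer libraries used, the cause was not tested.

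With the replicate number as a replicate block, 190 regions were called in jmj28-2 and 251 in atx1/2. The residuals of libraries with the same number correlated at -0.0156, 0.0199 and -0.0116 between genotypes, so the numbers did not pair them and the unblocked fit was kept.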

Other observations

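Genes and tests in this part were chosen after the result was seen. Among the 46 regions with a peak in both libraries of each mutant and in neither Col-0 library, a few were picked as single genes, with no test of a shared function. They were GA3OX1, a gibberellin synthesis gene (1391 and 1351 bp in jmj28-2, 1400 and 1390 bp in atx1/2), the auxin-responsive IAA19 (1065 and 1101 bp, 1201 and 1189 bp) and the MADS-box gene SEP4 (1237 and 1280 bp, 1359 and 1256 bp). ELIP2, an early light-induced gene, had 1346 and 1193 bp, and 1332 and 1368 bp. The cell cycle genes CDKB2;1 (1794 and 1852 bp) and MYB3R-4 (1440 and 1397 bp) had a peak in both Col-0 libraries and in no mutant library. AT3G21670 lost a longer peak in jmj28-2, with 3668 and 3700 bp in Col-0 and 3711 and 3614 bp in atx1/2.

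Regions without a protein-coding gene made up 5.67% of those lost and 9.46% of those gained in jmj28-2, and 6.31% and 11.7% in atx1/2, against 1.73% to 1.82% of other regions. Most of those others hold strong peaks, and among 501 other regions with a peak in 2 to 5 libraries the share was 6.19%. Against these none of the 4 groups passed the test (2-sided Fisher's exact test, adjusted p = 1, 0.626, 1 and 0.0876).

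A hypothesis was that cysteine-rich receptor-like kinase genes were over-represented among regions lost in jmj28-2. They made up 4 of 66 lost regions with a symbol, against 0.203 expected (1-sided Fisher's exact test, adjusted p = 0.0131). The adjustment covered 316 tests, of gene families in the lost and in the gained regions of both mutants. Without the 3 regions beside JMJ28 the adjusted p was 0.0793, with CRK21, CRK22 and CRK26 left. CRK21 and CRK22 are adjacent regions and not independent, so the test left the hypothesis open. In the same scan cytochrome P450 genes made up 6 of 65 regions gained in atx1/2, against 0.76 expected (adjusted p = 0.0158), and 4 of 34 gained in jmj28-2 (adjusted p = 0.0645). With equal numbers of peaks 1 of these 6 and 2 of these 4 stayed gained, and no P450 excess passed the test. Lost and gained regions mostly held weak peaks, but the background of the scan, 6503 regions, was not limited to regions with a peak in 2 to 5 libraries. Whether the receptor-like kinase or P450 excess holds against such regions was not tested.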
